A study of Homo sapiens with 6 samples.

How the data were processed

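The samples were 6 RNA-seq libraries of MHCC97H cells, 3 treated with the vehicle DMSO and 3 treated with 2 µM FB23-2 for 48 h. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was enriched on oligo(dT) beads, fragmented and reverse-transcribed, and the libraries were sequenced as paired ends on an Illumina NovaSeq. The aligner HISAT2, the transcript assembler StringTie and the genome build GRCh38 are named in the submitters' processing notes, without versions, settings or an annotation. The deposited values are FPKM (mapped fragments scaled for transcript length and for the total of the library), computed by the authors, with 1 value per gene and library. Per the file headers, each column carries a group, a replicate number and the word input, which is the usual name for the RNA set aside before immunoprecipitation in MeRIP-seq. The series design names MeRIP-seq as a further assay, and it was not analysed here.

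The sequencing depth per sample is unknown. The table used here holds FPKM alone, and low values of genes with a single transcript, multiplied by transcript length, were not whole multiples of a common step, so whole reads could not be recovered. No counting interval or detection floor is therefore given, and the precision stated is the spread between the 3 libraries of a group. The median standard error of the log2 changes was 0.06. FPKM divides by the library's own total, so a change in a few abundant genes moves all other values, and genes with near-identical copies can exchange reads.

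From the FPKM table, values were transformed to log2(FPKM + 1), and a gene was tested when it reached at least 1 FPKM in at least 3 of the 6 libraries, which left 12132 of 30468 genes. FB23-2 was compared with DMSO in limma 3.58.1 (R 4.3.3) with moderated variances that follow a mean trend, treatment as the only term, two-sided tests and Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low genes. FTO, ERBB3 and TUBB4A were also compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1. The groups share replicate numbers, but no label says that a number marks a shared culture or day, so no block was used in the main comparison.

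In all, 39 gene lists were fixed, covering the m6A machinery, the genes of the series title, liver function, metabolism, stress and signalling responses, the cell cycle, RNA quality and markers of other cell types. Lists with at least 5 tested members were compared with all other tested genes by limma's camera test with a preset correlation between genes of 0.01, and again with an estimated correlation. Camera p-values were adjusted over the tested lists. Each list's own members were also tested by fry, limma's rotation test. Members called were counted over all tested genes and adjusted over the list alone. GO and KEGG terms came from the annotation columns of the table, and terms with 10 to 500 tested genes were compared by a one-sided hypergeometric test, separately for higher and lower genes, with adjustment over all 4104 tests. The GO background was 8925 tested genes with an entry and the KEGG background 4307. GO entries of 2195 genes were not used here. Gene types, GC content and transcript lengths came from GENCODE 29, in which 12065 of the tested genes had a match. Coordinates are those of the table, counted from 1 on GRCh38.

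The genes named were FTO, ERBB3 and TUBB4A, then the 8 higher and 8 lower called genes with the largest log2 change among genes with a symbol that is not a clone, locus or LINC name, a mean of at least 1 FPKM and no overlap between groups. For each list, up to 4 called members with the smallest p followed, and all members of the m6A lists could be given. The grouping, the test, the filter, the pseudocount, the lists, this rule and most alternatives were chosen before the data were examined. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, rescaling every library to the same sum, median centring, quantile normalisation, variances without a trend, library weights, the replicate number as a block, protein-coding genes only, a minimum absolute log2 change of 1, and leaving out each library in turn. A GC and length correction, list counts without DMSO replicate 3, and term counts with a library left out or with the block were added after the values had been seen.

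The procedure was tested on simulated data with the real genes and spreads of this comparison (12132 genes, 50 changed genes per size). It recovered 28% of genes changed by a log2 of 0.25, 74% at 0.5, 100% at 1 and 96% at 2. Of 154 calls, 5 were false, and a simulation with no change gave 0 calls. The real comparison gave 4304 calls, so its threshold was less strict and these recovery shares do not carry over to it. Genes were drawn independently, so false calls from effects shared within a library were not tested.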

Results

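RNA-seq was carried out on MHCC97H cells, a human hepatocellular carcinoma line known for its high metastatic potential, after 48 h with 2 µM FB23-2 or with its vehicle, DMSO. FB23-2 is described in the series design as an inhibitor of FTO, an enzyme that removes the methyl mark m6A from RNA. Each group held 3 libraries, and expression was given in FPKM for 30468 genes. FPKM summed to between 183697 and 187647 per library, 11922 to 12026 genes reached 1 FPKM, and the 10 most abundant genes held 4.33% to 4.60% of the sum. Sequencing depth is unknown. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.990 to 0.992 within a group and 0.978 to 0.981 between groups. The labels do not say whether the libraries of a group came from separate cultures. If they did not, p-values measure only the spread between these samples, which may be technical.

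The comparison of FB23-2 with DMSO served to find transcripts that respond to the compound. All 23 tested genes of cholesterol synthesis and its regulator SREBP2 were lower in FB23-2, together with most genes of fatty acid synthesis and the urea cycle genes ASS1 and CPS1. The immediate-early genes EGR1 and FOS and the matricellular genes CCN1 and CCN2 were higher. So were most tested genes of heat shock (12 of 14), replication-dependent histones (10 of 11) and ribosome biogenesis (65 of 89). In limma, 4304 of 12132 tested genes (35.5%) were called, 2651 higher and 1653 lower. Sizes were modest on the log2(FPKM + 1) scale, with a median absolute log2 change of 0.26 among called genes. On that scale 73 genes changed by a log2 of at least 1, 38 of them higher and 35 lower. The scale understates changes of low genes. The 73 therefore leave out called genes with large FPKM changes, such as ERBB3 (2.30-fold lower) and IL6 (3.44-fold higher). The share of higher calls was 61.6%, but it moved with centring. After median centring 1970 genes were higher and 2043 lower (49.1% higher), and after quantile normalisation 2028 were higher and 1964 lower (50.8% higher). The values of the groups did not overlap in 6072 genes (50%), where chance gives 10%.

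ERBB3 encodes a receptor tyrosine kinase of the EGFR family, and it is one of the genes that the series title names as lowered. Its level was 2.00 ± 0.153 FPKM in DMSO and 0.869 ± 0.0512 FPKM in FB23-2 (mean ± SD, n = 3 per group throughout), which is 2.30-fold lower. ERBB3 (ENSG00000065361) lies on the plus strand of chromosome 12 from 56076799 to 56103505. Its log2 change was -0.68 (SE 0.07), with a limma adjusted p of 0.00069 and an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. ERBB3 passed the 1 FPKM filter through its DMSO levels alone, since its FB23-2 values were 0.812 to 0.911 FPKM. TUBB4A (ENSG00000104833), a beta-tubulin gene also named in the title, lies on the minus strand of chromosome 19 from 6494319 to 6502848. TUBB4A measured 0.703 ± 0.186 FPKM in DMSO and 0.377 ± 0.112 FPKM in FB23-2, and the ranges overlapped (0.497 to 0.858 against 0.285 to 0.502). It stayed below the 1 FPKM filter and was not tested in the main comparison. Its log2 difference was -0.30, with an exact permutation p of 0.2. Without the filter, limma gave TUBB4A an adjusted p of 0.172, and exact tests under the other alternatives gave p from 0.1 to 0.5.

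FTO (ENSG00000140718), on the plus strand of chromosome 16 from 53701692 to 54158512, had similar mRNA levels in both groups. FTO measured 2.10 ± 0.0706 FPKM in DMSO and 2.09 ± 0.175 FPKM in FB23-2. The log2 change was -0.01 (SE 0.06), with a limma adjusted p of 0.951 and an exact permutation p of 0.9. These values concern its mRNA and not its enzyme activity.

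**Figure D1:**
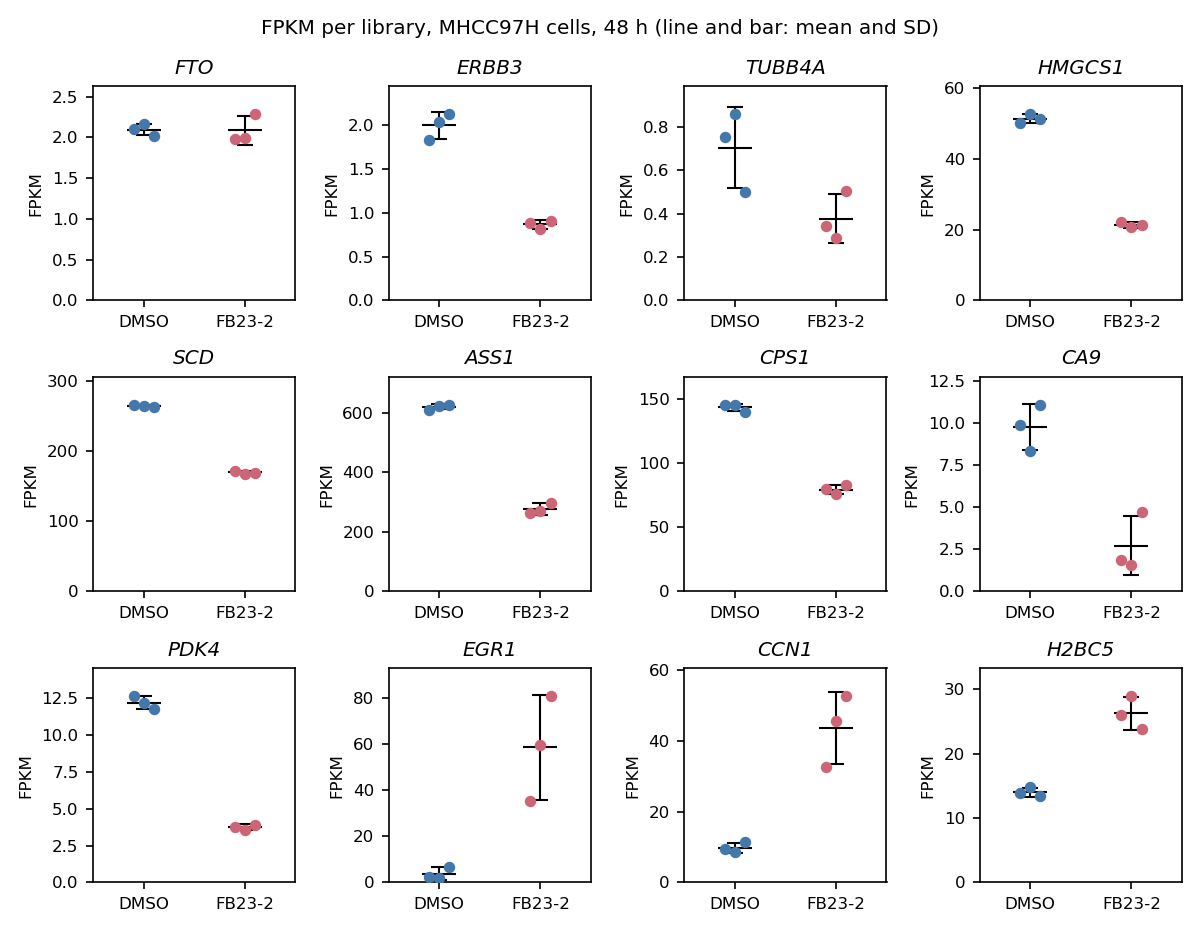
FPKM of 12 genes in each of the 3 DMSO libraries (blue) and 3 FB23-2 libraries (red), on axes that start at 0. The horizontal line is the mean and the bar the SD; the FTO and TUBB4A values of the groups overlap, and the other panels show no overlap.

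The 8 largest rises among the named genes were 4 rapidly induced growth-response genes and 4 short noncoding RNAs, with EGR1 clear of the others. EGR1, an immediate-early transcription factor, rose from 3.75 ± 2.75 to 58.7 ± 22.8 FPKM (log2 change 3.72, SE 0.42, limma adjusted p 0.000988). EGR1, FOS, CCN1 and CCN2 were highest among the DMSO libraries in replicate 3, where EGR1 read 6.91 FPKM against 2.45 and 1.88 FPKM. Without that library the DMSO mean of EGR1 was 2.17 FPKM and its log2 change 4.17. These 4 genes also climbed with replicate number within FB23-2, where EGR1 read 35.5, 59.8 and 80.9 FPKM. CCN2 rose from 5.02 ± 1.66 to 33.8 ± 11.7 FPKM, CCN1 from 9.83 ± 1.41 to 43.6 ± 10.2 FPKM and FOS from 2.40 ± 0.975 to 12.8 ± 4.31 FPKM. The noncoding RNAs were BCYRN1 (23.2 ± 2.50 to 109 ± 27.6 FPKM), RPPH1, the RNA of RNase P (log2 change 1.94), and the U1 genes RNU1-1 (log2 change 2.51) and RNU1-3 (log2 change 1.90). U1 has many near-identical copies, so its gene-level values are uncertain, and DMSO replicate 3 also stood apart for RNU1-1 and RPPH1. RNU1-1 read 0, 0.0911 and 4.15 FPKM in the DMSO libraries. The RNU1-1 call was lost without DMSO replicate 1 or 2 or FB23-2 replicate 1 or 2, the RPPH1 call without any library but DMSO replicate 3, and the RNU1-3 call without FB23-2 replicate 1. All 3 calls were lost without the filter, and the RNU1-1 call with the replicate number as a block (limma adjusted p 0.0501).

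The 8 largest falls among the named genes belonged to different lists or to none. CA9, a carbonic anhydrase induced by hypoxia, fell from 9.76 ± 1.36 to 2.71 ± 1.74 FPKM, and PDK4, a kinase that holds back pyruvate oxidation, from 12.2 ± 0.437 to 3.75 ± 0.181 FPKM (log2 change -1.47, SE 0.05, limma adjusted p 1.5e-05). ALPI, intestinal alkaline phosphatase, fell from 118 ± 1.49 to 38.0 ± 6.43 FPKM, although close relatives in the genome make its read assignment uncertain. INSIG1, an SREBP2 target, fell 2.72-fold from 69.5 ± 2.72 FPKM, and the imprinted long noncoding RNA H19 fell 2.52-fold from 393 ± 5.93 FPKM. The remaining 3 were USH1C (3.75-fold), PMCH (4.61-fold) and FGFBP1 (2.74-fold). The clone-named locus AC023509, picked out after its values were seen, had the lowest log2 change of the tested genes, -2.86 (limma adjusted p 0.0207), with 10.5 ± 8.08 FPKM in DMSO and 0.171 ± 0.296 FPKM in FB23-2.

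**Figure D2:**
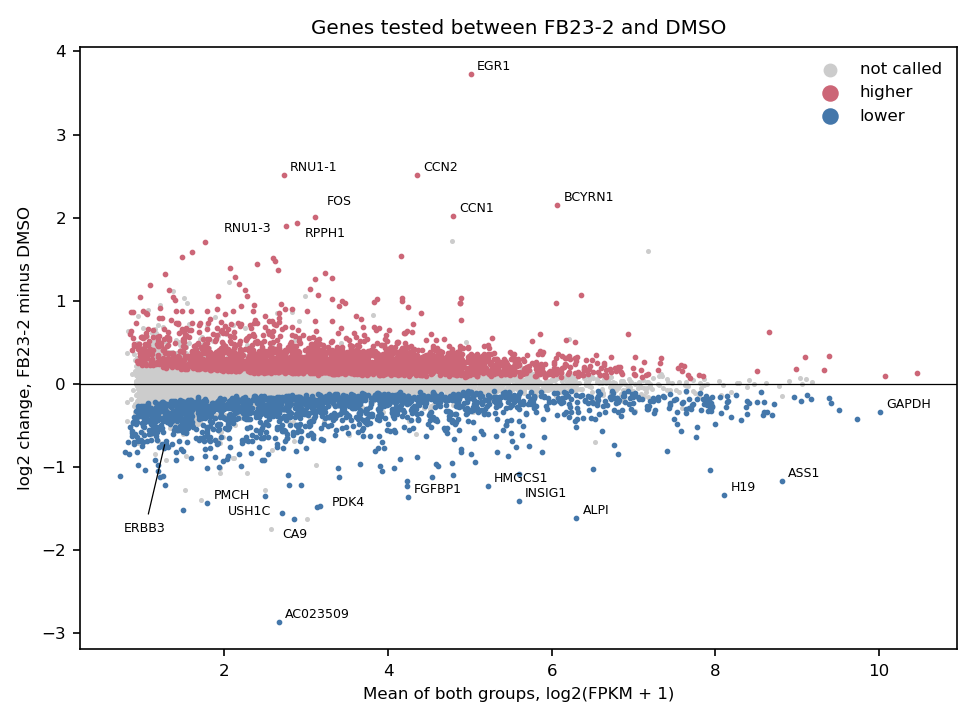
Log2 change of each tested gene (FB23-2 minus DMSO, vertical axis) against its mean level in both groups as log2(FPKM + 1), with called higher genes in red, called lower genes in blue and other genes in grey. EGR1 stands highest at 3.72 and AC023509 lowest at -2.86, and ERBB3 lies at -0.68 among genes of low level.

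Lipid synthesis genes fell together. Of the cholesterol synthesis and SREBP2 targets, all 23 tested members fell, also when adjusted over the list alone, with a median log2 change of -0.72. HMGCS1, which makes the precursor of mevalonate, fell from 51.3 ± 1.29 to 21.3 ± 0.727 FPKM (2.41-fold, limma adjusted p 1.5e-05), IDI1 from 31.3 ± 0.490 to 15.3 ± 0.364 FPKM, and FDPS from 74.3 ± 1.72 to 41.6 ± 0.529 FPKM. Camera gave this list an adjusted p of 2.3e-23 (adjusted p = 0.114 with an estimated correlation). In fatty acid synthesis, 12 of 15 tested members fell and 1 rose, with the same counts adjusted over the list alone. SCD, the desaturase that makes oleate, fell from 264 ± 1.38 to 170 ± 1.96 FPKM, FASN from 47.6 ± 0.745 to 30.5 ± 0.887 FPKM, and ACSS2 2.68-fold. The higher count was 0 whichever library was left out. The list's camera adjusted p was 5.1e-08 (adjusted p = 0.114 with an estimated correlation). Of 11 PPAR targets and fatty acid oxidation genes, PDK4, ACSL1 and HADHA fell, 3 also adjusted over the list alone, and the other 8 did not pass (camera adjusted p 0.0215; adjusted p = 0.240 with an estimated correlation).

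Of the 34 genes on the hepatocyte list, only 5 passed the filter, AMBP and HNF4A through their DMSO levels alone. Of these, ASS1 fell from 620 ± 8.25 to 277 ± 19 FPKM, CPS1 from 143 ± 3.10 to 79.4 ± 3.34 FPKM, and AMBP and the transcription factor HNF4A fell from 1.31 and 1.19 FPKM to 0.400 and 0.470 FPKM. The count was 4 lower over all genes and 5 lower adjusted over the list alone, with a median log2 change of -0.72. Camera gave an adjusted p of 2.8e-05 (adjusted p = 0.114 with an estimated correlation), and 0.106 without the filter. Then 24 hepatocyte members entered, 5 fell and 2 rose, and the median log2 change was 0.00. Liver cancer and fetal liver markers were mixed, with 3 of 8 lower (H19, CD24 and PEG10) and 2 higher (DKK1 and GOLM1), the same adjusted over the list alone (camera adjusted p 0.229).

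Genes of glycolysis, hypoxia and amino acid supply were lower on balance. In glycolysis 12 of 19 tested members fell and 2 rose (14 and 3 adjusted over the list alone): ALDOC fell 2.08-fold and GAPDH 1.26-fold from 1153 ± 17.0 FPKM, whereas HK1 rose from 25.3 ± 0.919 to 32.7 ± 0.838 FPKM. Its camera adjusted p was 4.4e-05 (adjusted p = 0.235 with an estimated correlation). The hypoxia response had 10 of 16 lower and 2 higher, likewise adjusted over the list alone, including DDIT4 (65.0 ± 6.74 to 30 ± 2.43 FPKM) and BNIP3L (1.57-fold), with a camera adjusted p of 7.7e-05 (adjusted p = 0.282 with an estimated correlation). Of 21 genes in the ATF4 and amino acid response, 11 fell (12 adjusted over the list alone), among them CTH, PHGDH and TRIB3 (1.83-fold, 1.35-fold and 1.60-fold). The camera adjusted p was 2.1e-05 (adjusted p = 0.153 with an estimated correlation). The ATF4 count was 6 without DMSO replicate 3 and 7 without DMSO replicate 1 or FB23-2 replicate 2, and only 1 hypoxia gene rose without any library but DMSO replicate 1.

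Endoplasmic reticulum chaperones and antioxidant genes also fell. In the unfolded protein response list 10 of 18 fell (13 adjusted over the list alone), with HSP90B1 going from 205 ± 4.19 to 153 ± 4.92 FPKM and PDIA6 from 89.4 ± 1.14 to 66.7 ± 1.41 FPKM (camera adjusted p 1.6e-07; adjusted p = 0.153 with an estimated correlation). Of 17 NRF2 targets, 12 fell and 1 rose, with the same counts adjusted over the list alone. AKR1C2 fell 1.57-fold, TKT 1.37-fold and the quinone reductase NQO1 1.25-fold (camera adjusted p 3.9e-07; adjusted p = 0.114 with an estimated correlation). Ferroptosis regulators had 7 of 14 lower and 2 higher, as adjusted over the list alone: the transferrin receptor TFRC fell from 116 ± 4.62 to 77.8 ± 1.26 FPKM, and HMOX1 and the lipoxygenase ALOX15 fell (camera adjusted p 0.00736; adjusted p = 0.241 with an estimated correlation). ALOX15 passed the filter through its DMSO levels alone, with a mean of 1.27 FPKM in DMSO and 0.0501 FPKM in FB23-2. Without DMSO replicate 2, 0 NRF2 targets and 1 ferroptosis gene rose.

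Cytosolic chaperones, MYC targets and growth-response genes rose. Of 14 heat shock genes 12 rose (13 adjusted over the list alone), with HSPA8 going from 315 ± 9.41 to 486 ± 25.1 FPKM and HSP90AA1 from 482 ± 5.39 to 606 ± 1.78 FPKM (camera adjusted p 5.1e-07; adjusted p = 0.114 with an estimated correlation). Of 25 MYC targets 18 rose (20 adjusted over the list alone), such as nucleolin NCL (1.21-fold), ODC1 (1.26-fold) and LYAR (1.58-fold). Their camera adjusted p was 3.1e-06 (adjusted p = 0.153 with an estimated correlation), and median centring left 17 higher and 1 lower. Immediate-early genes had 10 of 18 higher (11 adjusted over the list alone) and 0 lower, including SPRY2 (1.73 ± 0.0524 to 5.36 ± 1.32 FPKM) and FOSL1 (2.09-fold), with a camera adjusted p of 0.00265 (adjusted p = 0.361 with an estimated correlation). YAP and TEAD targets had 8 of 13 higher and 1 lower (8 and 2 adjusted over the list alone), among them CCN1, CCN2 and TGFB2, with a camera adjusted p of 0.0215 (adjusted p = 0.345 with an estimated correlation); without DMSO replicate 3 or FB23-2 replicate 2, 0 were lower. FOS, EGR1, CCN1 and CCN2 are also genes that respond within minutes to hours to medium change or handling.

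Cytosolic ribosomal protein genes and ribosome assembly genes moved in opposite directions. Of 32 cytosolic ribosomal protein genes 24 fell and 0 rose (29 lower adjusted over the list alone), with RPS3 going from 170 ± 1.44 to 133 ± 0.949 FPKM and RPLP0 from 265 ± 1.93 to 212 ± 7.78 FPKM. The camera adjusted p was 1.6e-13 (adjusted p = 0.282 with an estimated correlation), and quantile normalisation gave 20 lower and 4 higher. Among GO terms, ribosome biogenesis held 65 higher genes of 89, against 20.6 expected (hypergeometric adjusted p 1.5e-20), and the small-subunit processome 29 of 35, against 8.08 expected. The KEGG ribosome term held 63 lower genes of 129, against 22.1 expected (adjusted p 1.3e-14).

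Most histone transcripts and some mitochondrial transcripts, which can mark RNA quality or poly(A) selection, were higher in FB23-2. Of 11 tested replication-dependent histone genes 10 rose, also adjusted over the list alone and without DMSO replicate 3, with a median log2 change of 0.85. H2AC6 rose from 8.56 ± 0.912 to 18.0 ± 0.838 FPKM and H2BC5 from 14 ± 0.683 to 26.2 ± 2.61 FPKM (camera adjusted p 2.3e-05; adjusted p = 0.147 with an estimated correlation). Most of these mRNAs lack a poly(A) tail, and histone genes share sequence, so their reads are uncertain. Of 15 mitochondrially encoded genes 6 rose and 9 did not pass, also adjusted over the list alone, such as MT-CO2 (20 ± 0.286 to 29.4 ± 0.806 FPKM), with a camera adjusted p of 0.0303 (adjusted p = 0.439 with an estimated correlation). That call was lost without DMSO replicate 1 (adjusted p 0.130, with 1 gene lower) or FB23-2 replicate 3 (adjusted p 0.0586, 3 higher). MT-CO2 stood at 20 FPKM in DMSO, beside 1153 FPKM for GAPDH. The processing notes give no settings, so it is unknown whether mitochondrial reads were kept in full. These values may therefore not reflect RNA quality or the level of mitochondrial transcripts. Nuclear genes of oxidative phosphorylation had 8 of 28 lower and 2 higher (8 and 3 adjusted over the list alone), with COX6C falling 1.16-fold (camera adjusted p 0.0303; adjusted p = 0.450 with an estimated correlation). This call was lost without DMSO replicate 2 (adjusted p 0.0598, 3 lower) or FB23-2 replicate 1 (adjusted p 0.109) and in the fry test (adjusted p 0.123), and 4 were lower without DMSO replicate 1, 5 without DMSO replicate 3 or FB23-2 replicate 2.

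The m6A machinery changed little. Of 12 writer genes 7 rose, also adjusted over the list alone, by at most a log2 of 0.29 in METTL5; WTAP rose 1.14-fold and PCIF1 1.18-fold. The catalytic subunit METTL3 measured 4.08 ± 0.242 and 3.97 ± 0.276 FPKM and its partner METTL14 3.31 ± 0.372 and 3.42 ± 0.323 FPKM, and neither passed. The camera adjusted p was 0.0260 (adjusted p = 0.208 with an estimated correlation), and 0.0546 without DMSO replicate 1. The count of writers fell to between 2 and 5 when any library was left out, to 3 without DMSO replicate 3, and to 4 after median centring. Of 15 erasers and readers 6 rose and 1 fell, as adjusted over the list alone, and the list was not called (camera adjusted p 0.189), except without the filter (adjusted p 0.0245). The other m6A demethylase, ALKBH5, rose from 18.2 ± 0.353 to 22.8 ± 1.23 FPKM, YTHDF1 rose 1.28-fold, and HNRNPA2B1 fell 1.14-fold. The HNRNPA2B1 call was lost after quantile normalisation.

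Lists built around the title genes were mixed, and their counts stand beside 35.5% called over all tested genes. Of 6 tested ERBB receptors and ligands, ERBB3 fell, and EGFR (23.0 ± 0.451 to 26.0 ± 0.996 FPKM) and the ligands HBEGF and AREG rose. AREG passed the filter through its FB23-2 levels alone. Adjusted over the list alone, 2 fell and 3 rose. The median was 0.03 while the mean was slightly below 0 and the test pointed down (camera adjusted p 0.897). Of 14 tubulins, TUBA1B (377 ± 7.71 to 293 ± 5 FPKM), TUBB, TUBA1A and TUBA1C fell and 1 rose, as adjusted over the list alone, and the list was not called (camera adjusted p 0.0843), although it passed without DMSO replicate 3 (adjusted p 0.0498). No tubulin rose without DMSO replicate 2 or 3 or FB23-2 replicate 2, and 2 rose without DMSO replicate 1. Of 19 AKT and mTOR pathway genes 4 fell, including AKT1 (1.22-fold), and 2 rose, as adjusted over the list alone, and the median (0.01) and the test (down) differed in sign (camera adjusted p 0.371). Leaving out DMSO replicate 2 or 3 or FB23-2 replicate 1 or 2 left 2 of these genes lower, and 1 rose without DMSO replicate 2 or any FB23-2 library. Of 5 genes reported to act downstream of FTO in leukaemia, LDHB fell, also adjusted over the list alone, and the list was not called (camera adjusted p 0.196). The LDHB call was lost after quantile normalisation.

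Cell cycle genes went both ways. Of 34 G1/S and DNA replication genes 11 rose and 8 fell (13 and 8 adjusted over the list alone), with RRM2 rising from 18.7 ± 0.837 to 27.4 ± 1.06 FPKM and TK1 falling 1.18-fold (camera adjusted p 0.336). The lower count was 4 or 5 when any library other than DMSO replicate 1 was left out. Of 34 G2/M and mitosis genes 6 rose and 9 fell (6 and 12 adjusted over the list alone): CDK1 rose from 63.2 ± 1.39 to 78.5 ± 2.68 FPKM and KIF20A fell 1.27-fold. The G2/M list was not called (camera adjusted p 0.0789), but it passed as lower without DMSO replicate 1 (adjusted p 0.0243) or FB23-2 replicate 3 (adjusted p 0.0154) and after GC and length correction (adjusted p 0.0402). Without DMSO replicate 2 or 3, 4 fell.

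Stress, survival and signalling lists that were not called in the main comparison held changed genes too. Since 35.5% of all tested genes were called, a count near that share does not set a list apart. Of 21 p53 targets 4 fell and 2 rose (3 and 2 adjusted over the list alone), with BTG2 falling from 7.29 ± 0.840 to 3.84 ± 0.0819 FPKM; the median was 0.02 while the test pointed down (camera adjusted p 0.551), 2 fell without DMSO replicate 3 or FB23-2 replicate 2, and 1 rose without DMSO replicate 2 or FB23-2 replicate 2. Of 18 apoptosis regulators 5 rose, among them MCL1 (1.24-fold), and 2 fell, among them CASP9 (1.53-fold), as adjusted over the list alone (camera adjusted p 0.742). Epithelial-mesenchymal transition genes had 8 of 14 higher and 1 lower (8 and 2 adjusted over the list alone): the tight junction gene CLDN1 rose 2.28-fold and the repressor SNAI2 fell 1.56-fold (camera adjusted p 0.210), and 3 fell without FB23-2 replicate 1. The interferon response had 6 of 15 higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p 0.989). NF-kB and inflammation genes had 4 of 14 higher and 1 lower, as adjusted over the list alone (camera adjusted p 0.200). IL6 was among the higher genes (0.489 ± 0.0819 to 1.68 ± 0.318 FPKM) and passed the filter through its FB23-2 levels alone. In this list 6 rose without FB23-2 replicate 3, and 0 fell without DMSO replicate 1 or 2 or FB23-2 replicate 2. Xenobiotic response genes had 3 of 7 higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p 0.210). Of 8 WNT targets AXIN2 (2.61-fold) and GLUL fell and DKK1 rose, as adjusted over the list alone (camera adjusted p 0.210, and 0.0161 without the filter). Of 21 autophagy and lysosome genes 6 fell, among them ULK1 (1.63-fold), and 3 rose (7 and 5 adjusted over the list alone; camera adjusted p 0.184), and 1 rose whichever library was left out.

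Markers of other cell types were scarce. No immune marker was tested, since all 11 in the table averaged under 1 FPKM and CD68 was highest at 0.455 FPKM. Of the fibroblast markers 4 were tested and COL1A1 and COL5A1 fell (1 higher and 2 lower adjusted over the list alone), with 1 lower without DMSO replicate 2 or 3 or FB23-2 replicate 2 or 3. COL1A1 passed the filter through its DMSO levels alone. Of the endothelial markers ESAM rose and EGFL7 fell, also adjusted over the list alone. Of 5 bile duct and stem cell markers KRT7 and MUC1 fell (3 adjusted over the list alone), with a camera adjusted p of 0.0368 (adjusted p = 0.282 with an estimated correlation) and 0.0581 without FB23-2 replicate 2. Of these markers 0 fell without DMSO replicate 1, and 1 fell without DMSO replicate 2 or FB23-2 replicate 1 or 2. KRT7, MUC1, ESAM and COL5A1 can also be expressed by carcinoma cells.

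**Figure D3:**
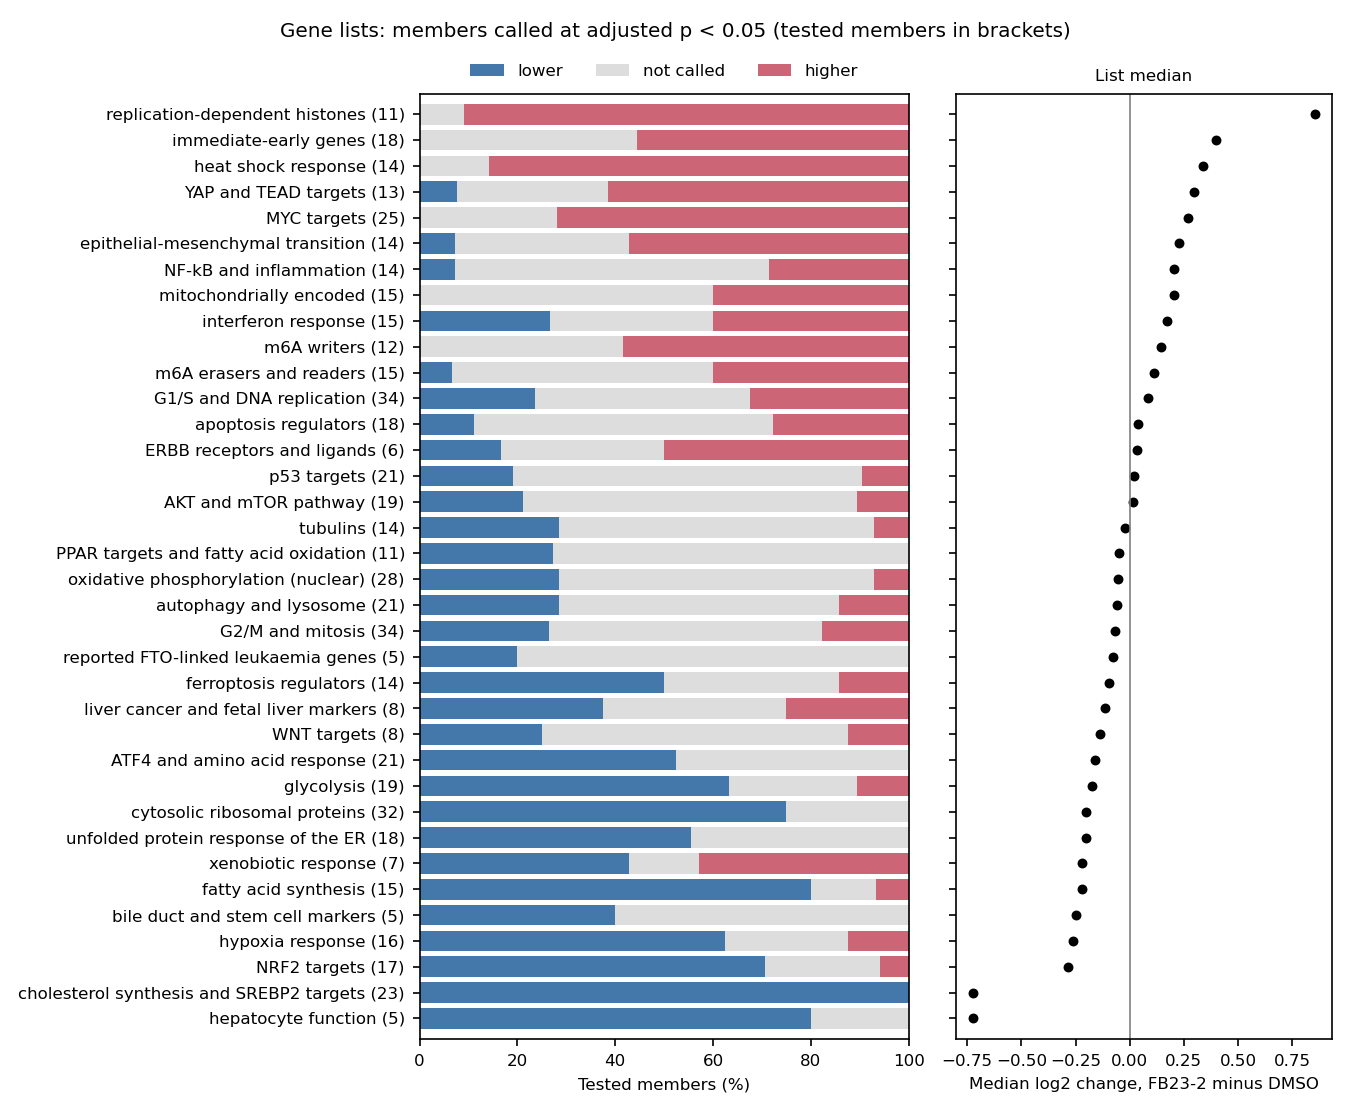
Left, share of the tested members of each of 36 gene lists called lower (blue), higher (red) or not called (grey), in percent, with the number of tested members in brackets. Right, the list's median log2 change (FB23-2 minus DMSO); the cholesterol list stands at -0.72 with all members lower, and the histone list at 0.85.

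Across annotation terms, 134 passed the hypergeometric test, 62 for higher and 72 for lower genes. Besides ribosome assembly, terms of RNA handling were enriched among higher genes: mRNA processing held 119 of 304, against 70.2 expected (adjusted p 2.6e-08), and RNA splicing 99 of 246, against 56.8 expected. The GO term for mRNA methylation held 9 higher genes of 14, against 3.23 expected (adjusted p 0.0379). Term tests treat genes as independent and were not repeated after median centring, which left 4 of the 12 m6A writers higher. Among lower genes, protein targeting to the membrane by the signal recognition particle held 56 of 82, against 11 expected (adjusted p 9.8e-27), a term made up largely of ribosomal proteins. Cholesterol biosynthesis held 18 of 23, against 3.09 expected, focal adhesion 68 of 214, against 28.7 expected, and collagen-containing extracellular matrix 31 of 84, against 11.3 expected. With genes changed by a log2 of at least 1, 13 terms passed, led by the nucleosome (7 higher genes of 49, against 0.0714 expected).

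Camera called 20 of 36 tested lists, 7 higher and 13 lower, and 0 with an estimated correlation, where 9 lists had an unadjusted p under 0.05. Fry, which asks whether a list's own genes move one way on balance, called 29, and its mixed test called all 36; neither compares a list with other genes.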

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

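The GC and length correction, list counts without DMSO replicate 3 and term counts with a library left out or with the block were chosen after the result was seen. The genes called numbered 3109 to 3562 with a library left out, 1900 to 2223 of them higher and 1209 to 1396 lower. The number was 3141 without the filter, 3186 with a mean of at least 5 FPKM, 4152 without a variance trend, 4496 with library weights, 4013 after median centring and 4342 after GC and length correction. With the replicate number as a block, a pairing that the labels do not describe, 3918 genes were called (2400 higher and 1518 lower), 3679 of them also called without it, and deviations from the group mean in libraries of the same number had r of -0.02, -0.06 and -0.04 across genes. With a minimum absolute log2 change of 1, 73 genes and 13 terms passed. Camera called 19 to 21 lists with a library left out, 20 with the block, 21 without the filter and 0 with an estimated correlation. Terms numbered 105 to 127 with a library left out and 128 with the block. ERBB3 kept its call in all alternatives that tested it, with log2 changes from -0.65 to -1.11. TUBB4A ranged from -0.24 to -0.75. Of 163 named genes 136 stayed on the same side of the threshold throughout, called or not, and no call reversed; ZC3H13 changed in 14 of 19 alternatives, CBLL1 in 12 of 19, ZCCHC4 in 10 of 18, MTOR and COL5A1 in 9 of 19, RNU1-1 and RPPH1 in 7 of 18 and KRT7 in 7 of 19. Camera was not run with a pseudocount of 0.5, a mean of at least 5 FPKM, rescaling, quantile normalisation, no variance trend, library weights or protein-coding genes only; among the alternatives it was run with, no call of a list ended beyond those given with the list.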

Other observations

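The small RNA, EGR1, GC and length, and random list tests, and the use of the planned G1/S and left-out-library results as tests of an explanation, were chosen after the result was seen. The quiescence and starvation list was added after the main results too, with its prediction written before it was run.

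Unpolyadenylated small RNAs, a class that no list covered, were also higher on balance. Of 96 tested, 25 rose and 2 fell, against 2651 higher and 1653 lower of all 12132 tested genes. The class was not compared with other genes by a list test. RMRP, the RNA of a ribosomal RNA processing enzyme, rose by 1.51 on the log2 scale (limma adjusted p 0.000239), and RN7SK did not pass (log2 change 1.72, adjusted p 0.0554). RN7SK read 30.8 FPKM in DMSO replicate 3 against 6.06 and 5.93 FPKM in the other DMSO libraries. The signal recognition particle RNAs RN7SL1 and RN7SL2 did not pass either (log2 change 0.10 in both). Of 13 tested genes typical of quiescent or starved cells, 9 fell and 1 rose, with CCNG2 falling by 0.65, ARRDC3 by 0.55 and IRS2 rising by 0.30 on the log2 scale. SESN1, which is also among the p53 targets, did not pass.

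Histone transcripts rose by a median log2 of 0.85, which might come from more unpolyadenylated RNA carried into the FB23-2 libraries. The small RNAs had a median log2 change of 0.22 (95% bootstrap interval over genes 0.11 to 0.38), less than the histones. However, RMRP, RPPH1 and BCYRN1, 3 of 6 RNAs with their own promoters picked for this test, were called and exceeded the histone median. RN7SK exceeded it without a call. The U1 genes RNU1-1 and RNU1-3, not among the 6, were also called and exceeded it (log2 changes 2.51 and 1.90). More cells in S phase could also raise histones, and the G1/S list did not pass (camera adjusted p 0.336). Neither explanation can be told apart from an effect of FB23-2 with these libraries.

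Of the immediate-early genes 10 of 18 rose, and of the YAP/TEAD targets 8 of 13 rose and 1 fell (adjusted p = 0.361 and 0.345 with an estimated correlation), and handling at harvest could produce this if the groups were harvested in turn. The lowest EGR1 level in FB23-2 was 5.14 times the highest in DMSO, or 14.5 times without DMSO replicate 3. EGR1 was named by a rule that required no overlap between groups, so a ratio above 1 was fixed in advance. Harvest order is also unknown, and the ratio cannot separate the explanations. Within FB23-2, EGR1 rose with replicate number, and no label says what that number marks. Fewer cells, or medium less depleted after 48 h, may also matter: the quiescence and starvation list then should be lower, and its median log2 change was -0.21 (95% interval -0.28 to -0.14). Its camera p was 0.00073 (p = 0.064 with an estimated correlation), so culture density remains open as a cause, also for the lower hypoxia and sterol lists.

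The fall of the sterol list was not accounted for by GC content or length, by scaling between libraries or by 1 deciding library. Its median log2 change was -0.77 after GC and length correction, and 10000 random lists matched on expression ranged from -0.18 to 0.21, against -0.72 for the list. At least 22 of its 23 members were called lower with any library left out. These checks cannot detect a difference in culture, harvest or preparation that follows the groups. Random lists of unrelated genes also vary less than lists of genes that move together. Camera with an estimated correlation gave the sterol list an adjusted p of 0.114.

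The 10 possible splits into 3 and 3 libraries are too few for a share under 0.05. The real split gave 4304 called genes and the highest other split 1, so 1 of 10 was as large as the real one. For camera lists the real split gave 20 and the highest other split 14, again 1 of 10. The other splits called 5 to 14 lists, although none called more than 1 gene. Each of them still holds part of the treatment difference. Camera with the preset correlation thus called lists readily here, and its small p-values should be read with those from the estimated correlation.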
